A study of Mus musculus with 18 samples.

How the data were processed

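The series holds 18 ATAC-seq samples of mouse primary cortical neurons in 4 groups of 3 to 5, read as pairs of 50 bp, per the labels. The cultures received cytosine arabinoside at 2 µM, lentiviral shRNAs on day 6 and were taken on day 11, per the labels' protocols. The deposited file is 1 consensus list, and each interval is given with a start, an end, a name and a score. The peak names carry the name of MSPC, a program that combines peak calls across replicates, and the submitters' processing notes name MACS2, deepTools, MultiQC and the build mm10, without versions. The aligner, the shift of reads for the transposase, the handling of duplicate and mitochondrial reads, any list of excluded regions, the calling thresholds and which samples entered the consensus are not given in the sources used here. The deposited score is 1000 for 98.5% of peaks, and the other 3243 lie between 112.811 and 310.719. It was therefore used for no ranking or filter. How many samples had to share a peak is thus unknown, and a peak present in 1 group alone may or may not be in the list.

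Tests of counts per peak between the 4 groups, with their interaction, had been planned before the data were examined. They were not run, because the list has no values per sample or group, and no counts, depths or peak lists of single samples were used here. All values therefore describe the consensus set, have no standard deviation and no n of cultures, and cannot be assigned to a knockdown. The precision that sequencing depth gives is unknown.

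Gene positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 also names, with the outermost ends of 49997 genes. It holds no strand, exons or sequence. The planned promoter window became 1000 bp around either end of a gene, the planned upstream flank became 10 kb on both sides, and the planned exon, untranslated region and intron classes became gene end, inside a protein-coding gene, inside another gene only and between genes. Planned motif counts and the CpG-matched background were not run. Background sequence is the span from the first to the last peak or gene of each chromosome, gaps in the assembly included. Left out of the table were 17 genes without a chromosome and 348 genes on scaffolds (113 protein-coding), whose positions restart within a chromosome's entries. That filter was set after list results had been seen, and keeping the scaffold genes is among the alternatives. All 321 genes of the 18 lists were found, 1 of them (Micos10) by an older name.

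A gene counted as having a peak at an end if any base of a peak lay in the window. Each list was set against all other nuclear protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 18 lists and exact Clopper-Pearson 95% intervals. Genes are not replicates, and neighbouring genes can share a peak. Peaks per gene were compared with 10000 random lists drawn from about 200 genes nearest in length, a permutation test whose two-sided p is 2 times the smaller tail, adjusted in the same way. Class ratios divide the share of peak midpoints by the share of sequence and have intervals from 1000 bootstrap draws of 1 Mb blocks, as does the ratio of X to autosomes. Widths were compared within blocks that held at least 5 peaks of each kind, by the difference in mean width rank, with 100000 random flips of sign. A first version on block medians had given a small p on shuffled widths in the simulation and was replaced. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

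The genes named were set before the data were examined. They are Atf4 and Opa1, then of each list the 3 with the widest peak at an end and up to 3 with none in alphabetical order, then the 10 widest peaks. Of the genes this rule takes, 3 are not reported here. Other genes in the closing section were chosen after their values were seen.

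The methods were tested on simulated data. Peaks placed uniformly gave class ratios between 0.986 and 1.01 and 0 called lists over 21774 genes. Of 100 planted lists of 20 random genes with a gene-end share of 95%, 81 had unadjusted p under 0.05, as did 4 of 100 unchanged lists. With doubled peaks per gene, 83 of 100 planted and 3 of 100 unchanged lists had unadjusted p under 0.05. These rates are not those of the adjusted calls below, nor of smaller lists or lists of genes with a shared function. Gene-end peaks widened by 100 bp were recovered as 95 bp wider, and shuffled widths gave p = 0.435 (permutation test).

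Alternatives fixed before the data were examined were end windows of 500 and 2500 bp, peaks of at least 500 bp, a peak over the gene end itself, flanks of 2 and 50 kb, peaks away from gene ends, any overlap for classes, and chromosomes 1 to 19. Added after the data were seen were random lists matched on gene length, random lists matched on the number of protein-coding genes within 100 kb, leaving out peaks at another gene's end, leaving olfactory and vomeronasal receptors out of the background, and keeping scaffold genes.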

Results

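Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in primary cortical neurons of CD1 mouse embryos. Lentiviral short hairpin RNAs (shRNAs) were added on day 6 in culture and the cells were taken on day 11. The 18 samples fall into 4 groups. The group with a control and a scrambled shRNA, the group with the Opa1 shRNA and a scrambled shRNA, and the group with the Opa1 and Atf4 shRNAs each hold 5 samples, and the group with a control and the Atf4 shRNA holds 3. Opa1 is a GTPase of the inner mitochondrial membrane needed for its fusion and for cristae shape, and its knockdown is the mitochondrial stress of the design. Atf4 is the transcription factor of the integrated stress response.

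The design asks which accessible sites depend on Atf4, with and without Opa1 knockdown. The file analysed here is a single list of consensus peaks, with no column for a sample or a group, and which samples entered it is not given in the sources used here. None of the 4 pairwise comparisons between knockdown groups, and not their interaction, could be computed from it, and nothing below compares groups. No read depth is given in the file, so the depth of each sample is unknown. What follows describes which genes and regions lie in the consensus set of accessible sites of these cultures, against gene lists fixed before the data were examined. It has no replicates, so its intervals and p-values cover counting or the variation between genomic blocks, not the spread between cultures.

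The list held 211682 peaks (mm10), which covered 109.6 Mb. The median width was 425 bp, with quartiles of 308 and 625 bp and a range of 73 to 4410 bp, and 81103 peaks (38.3%) were at least 500 bp wide. The authors' score stood at its ceiling of 1000 for 208439 peaks (98.5%), so it could not rank peaks. Of 21774 nuclear protein-coding genes, 15320 (70.4%) had a peak within 1000 bp of either outermost end, and 3164 had none within 10 kb of the gene. The gene table used here gives no strand, so a gene end can be the start or the finish of transcription.

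Both targeted genes lay in accessible chromatin in the consensus set. Atf4 (chromosome 15, 80255184 to 80257545) had a peak of 1401 bp over its lower-coordinate end, from 80254738 to 80256138. A second peak of 434 bp, from 80258395 to 80258828, lay beyond its other end, and 6 peaks lay within 10 kb of the gene. Opa1 (chromosome 16, 29579281 to 29663127) had a peak of 1008 bp over its lower-coordinate end, from 29579109 to 29580116. A peak of 346 bp, from 29663055 to 29663400, lay over its other end, and 7 peaks lay in the gene or within 10 kb of it. An shRNA acts on RNA, so these peaks do not check the knockdowns.

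**Figure D1:**
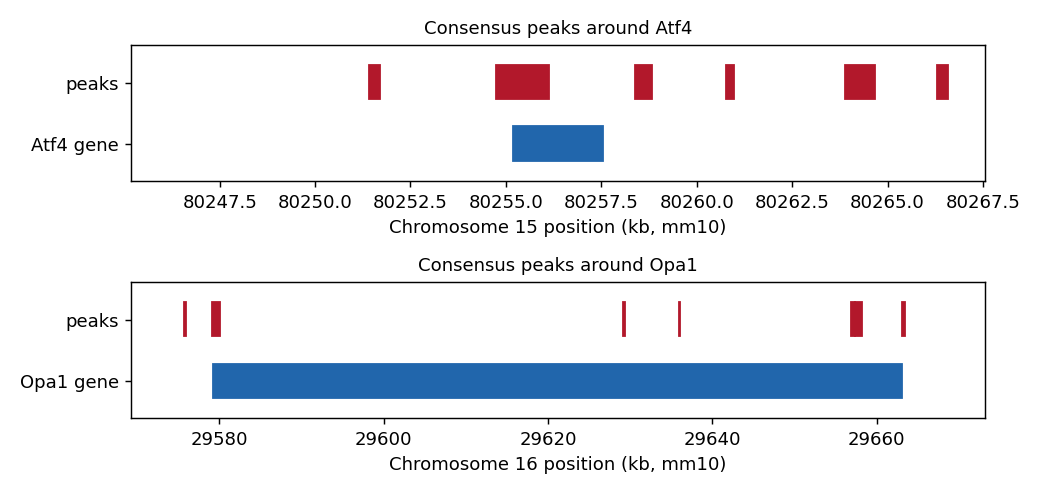
Consensus peaks (red) and gene extents (blue) at Atf4 on chromosome 15 and Opa1 on chromosome 16, with 10 kb on either side; the horizontal axes give the mm10 position in kb, and the gene bars span all exons and introns. A peak of 1401 bp covers one end of Atf4 and a peak of 1008 bp one end of Opa1.

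Stress and mitochondrial genes were compared with all other protein-coding genes, since the study is about a mitochondrial stress and the response Atf4 drives. Of 44 targets of Atf4 and the integrated stress response, 42 had a peak at a gene end (95.5%, exact 95% interval 84.5 to 99.4%), against 70.3% of other genes (adjusted p = 0.000431, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 18 lists). The widest were at Cebpb, a bZIP transcription factor (chromosome 2, 167687938 to 167690240, 2303 bp), at Vldlr, a lipoprotein receptor (chromosome 19, 27216184 to 27218343, 2160 bp), and at Sars, which encodes seryl-tRNA synthetase (chromosome 3, 108422807 to 108424872, 2066 bp). The Sars peak lay almost wholly outside the gene, whose lower-coordinate end is at 108424864. The members with no peak at an end were Eprs, another aminoacyl-tRNA synthetase, and Slc7a11, the cystine-glutamate exchanger. They had 11 and 13 peaks elsewhere in the gene or within 10 kb of it. This list, which counts Atf4 itself, stood above other genes under each of the 9 alternative settings tried (adjusted p from 0.000114 to 0.00413, Fisher's exact test or permutation with random lists). Such a share was not particular to it. Of families chosen after values were seen, 76 of 78 mitochondrial ribosomal protein genes, 38 of 40 proteasome subunits and 72 of 77 ribosomal proteins had a peak at an end. All 16 ionotropic glutamate receptor genes also had one, and the remaining families had lower shares, down to 2.84%. The planned CpG-matched background was not run.

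Of 38 nuclear genes of oxidative phosphorylation, 37 had a peak at an end (97.4%, exact interval 86.2 to 99.9%, adjusted p = 0.000431, Fisher's exact test), and Cox7a2, a cytochrome c oxidase subunit, did not. Uqcrh of complex III and Ndufv2 and Ndufa1 of complex I had the widest, at 2021, 1887 and 1707 bp. Those at Uqcrh and Ndufv2 lay outside the gene. Of 26 genes of mitochondrial dynamics and cristae, 25 had a peak at an end (adjusted p = 0.00722, Fisher's exact test). Among them were Micos10 (1381 bp) and the protease gene Spg7 (1377 bp). The exception was Oma1, the protease that cleaves Opa1. All 16 genes of the list of mitochondrial chaperones and proteases had a peak at an end (adjusted p = 0.0150, Fisher's exact test). That list also holds the import genes Tomm20, Timm17a and Timm23 and the mitochondrial DNA genes Tfam, Polg and Polg2. Tomm20, of the import receptor, had a peak of 1645 bp, and the chaperonin genes Hspd1 and Hspe1, which are neighbours, shared 1 peak of 1605 bp (chromosome 1, 55087218 to 55088822). Peaks within 1000 bp of another gene's end were then left out. This rule can also drop a peak at a gene's own end, as it does for the peak shared by Hspd1 and Hspe1. It can thus lower the share of lists with close neighbours. In that setting 24 of 38 oxidative phosphorylation genes and 10 of 16 genes of the chaperone list kept a peak, against 57.5% of other genes. Neither list stood apart (adjusted p = 0.739 and 0.964, the highest over the 9 alternatives, with lowest values of 8.73e-06 and 0.00363, Fisher's exact test). Both lists had a median of 5 protein-coding neighbours within 100 kb, against 4 for all protein-coding genes. Against random lists matched on that number, both still passed (adjusted p = 0.00144 and 0.0261, permutation). The chaperone call ended in 4 of the 9 alternatives, and the mitochondrial dynamics call in 1, the random lists matched on gene length (adjusted p = 0.0916 by permutation, the highest of the 9, with a lowest value of 0.00122).

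All 12 targets of the oxidative stress factor NRF2 had a peak at an end (adjusted p = 0.0422, Fisher's exact test). The widest were at Osgin1 (2061 bp, outside the gene), at G6pdx, which encodes glucose-6-phosphate dehydrogenase (1820 bp), and at the thioredoxin gene Txn1 (1498 bp). Of 15 genes of the endoplasmic reticulum stress response, 14 had one, which did not pass the threshold (adjusted p = 0.0774, Fisher's exact test). Xbp1, Pdia6 and Herpud1 had peaks of 1938, 1837 and 1776 bp, and Edem1 had none. The NRF2 call ended in 4 of the 9 alternatives (adjusted p from 0.0123 to 0.149, exact or permutation), and the endoplasmic reticulum list passed in 3, among them peaks of at least 500 bp (adjusted p from 0.0147 to 0.487 over the 9, exact or permutation).

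**Figure D2:**
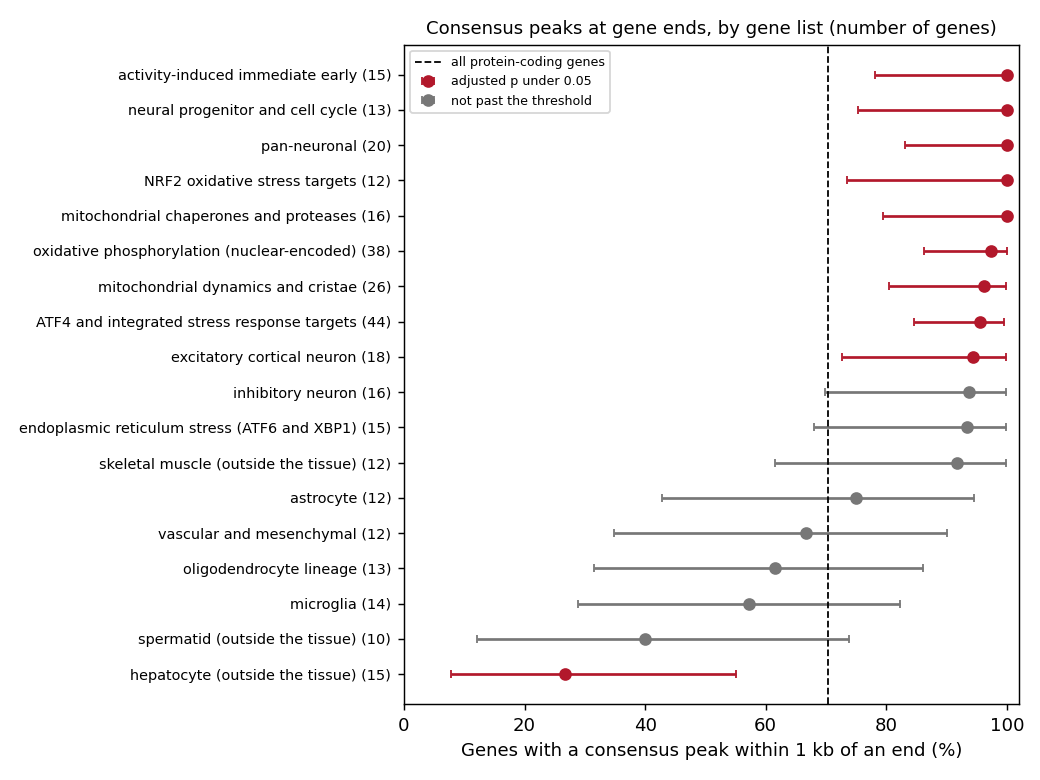
Percentage of genes with a consensus peak within 1000 bp of an end, for the 18 lists with the number of genes in brackets; points are shares, bars are exact 95% intervals, the dashed line is the share of all protein-coding genes (70.4%), and red marks lists past adjusted p 0.05 by Fisher's exact test. The list of Atf4 targets sits at 95.5% and the hepatocyte list at 26.7%.

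Marker lists of cell types were compared in the same way. A high share at gene ends does not identify a cell type, since 11 of 12 skeletal muscle genes, from outside the tissue, also had a peak. All 20 pan-neuronal genes had a peak at an end (adjusted p = 0.00498, Fisher's exact test), the widest at the synaptic vesicle gene Syp (2184 bp), the glutamate receptor gene Grin2b (1982 bp) and the RNA-binding protein gene Elavl4 (1887 bp). Of 18 excitatory cortical neuron markers, 17 had one (adjusted p = 0.0415, Fisher's exact test). Tbr1, Cux1 and Foxp2, which are transcription factors of cortical layers, had peaks of 2112, 1958 and 1865 bp. All 15 activity-induced immediate early genes had one (adjusted p = 0.0216, Fisher's exact test). The widest were 2100 bp at the nuclear receptor gene Nr4a1 and 2055 and 1738 bp at the AP-1 genes Junb and Fosb. Those at Nr4a1 and Junb lay wholly outside the gene, and that at Fosb mostly outside. All 13 neural progenitor and cell cycle genes also had a peak at an end (adjusted p = 0.0315, Fisher's exact test). They had 2197 bp at Sox2, 1593 bp at Vim and 1439 bp at Mki67. Cytosine arabinoside, which kills dividing cells, had been given to the cultures. None of these 4 lists passed against random lists matched on gene length. Over the 9 alternatives the call ended in 1 for pan-neuronal, 4 for excitatory, 4 for immediate early and 5 for progenitor genes, with the highest adjusted p at 0.0916, 0.195, 0.384 and 0.182 and the lowest at 0.000527, 0.00413, 0.00274 and 0.00413 (exact or permutation).

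Of 16 inhibitory neuron markers, 15 had a peak at an end, which missed the threshold (adjusted p = 0.0774, Fisher's exact test). The homeobox gene Dlx1 had a peak of 2431 bp, the widest end peak of this list, followed by Reln (2135 bp) and the glutamate decarboxylase gene Gad2 (1593 bp), and Pvalb had none. This list passed in 2 of the 9 alternatives, with 500 bp windows and when peaks at another gene's end were left out (adjusted p from 0.0110 to 0.511 over the 9, exact or permutation). Of the astrocyte list, 9 of 12 genes had a peak (widest at Fgfr3, Slc1a2 and Gfap, none at Aldh1l1, Aqp4 or Slc4a4). Of the oligodendrocyte lineage, 8 of 13 had one (widest at Mbp, Ugt8a and Olig1, none at Cspg4, Mag or Mobp, among others). Of the vascular and mesenchymal list, 8 of 12 had one (widest at Flt1, Col1a1 and Kdr, none at Col1a2, Lum or Pecam1, among others). Of the microglia list, 8 of 14 had one, with the transcription factor gene Sall1 at 1791 bp and none at Aif1, C1qb or P2ry12, among others. None of these 4 lists passed the threshold (adjusted p = 1, 0.613, 0.802 and 0.454, Fisher's exact test). The microglia list was lower than other genes in 2 of the 9 alternatives, at 28.6% with peaks of at least 500 bp and 21.4% with a peak over the end itself (adjusted p from 0.0191 to 1 over the 9, exact or permutation).

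The 3 lists from outside the tissue were set against all other genes in the same way as the rest. Of 15 hepatocyte genes, 4 had a peak at an end (26.7%, exact interval 7.79 to 55.1%), fewer than other genes (adjusted p = 0.00358, Fisher's exact test), and Ahsg, Alb and Cps1 were among those without. Among those with one, the apolipoprotein genes Apoa1 and Apoa2 had peaks of 1238 and 744 bp. Spermatid genes had one in 4 of 10 cases (adjusted p = 0.103, Fisher's exact test), with Gapdhs, Spata18 and Ldhc having one and Akap4, Pgk2 and Prm1 among those without. Skeletal muscle genes had one in 11 of 12 cases (adjusted p = 0.161, Fisher's exact test), and Myh2 had none. Actn3, Acta1 and Mylpf had the widest at 1122, 1030 and 1004 bp, that at Actn3 outside the gene. With a window of 2500 bp the hepatocyte share was 53.3% and no longer past the threshold (adjusted p from 0.002 to 0.103 over the 9 alternatives, exact or permutation). With peaks of at least 500 bp the spermatid share was 20% and passed it (adjusted p from 0.0137 to 0.659 over the 9, exact or permutation).

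The number of peaks in a gene and the 10 kb on either side gave a second measure, less tied to promoters. It was higher than in 10000 random lists matched on gene length for 2 lists. Inhibitory neuron markers had a median of 9 peaks per gene, against 4 in the random lists, and activity-induced immediate early genes also had 9 against 4. Each had p = 0.0002 by permutation, the smallest these random lists can give, and adjusted p = 0.0018. Reln had 68 peaks and Dlx1 8, and Nr4a1 had 12 and Junb 6. In the inhibitory list the windows of Dlx1 and Dlx2 overlap, as do those of Dlx5 and Dlx6, so a peak can count for both genes. The random lists were drawn gene by gene and do not copy this sharing. Excitatory markers had a median of 12 against 7 (adjusted p = 0.0768), progenitor genes 7 against 4 (adjusted p = 0.0846), pan-neuronal genes 17 against 11.5 (adjusted p = 0.441) and Atf4 targets 6 against 4 (adjusted p = 0.249), all by permutation with the random lists. Hepatocyte genes had a median of 2 against 4 (adjusted p = 0.249, permutation), and no other list passed the threshold. With flanks of 50 kb the inhibitory list was at 20.5 peaks and no longer passed (adjusted p from 0.0018 to 0.0708 over 3 alternatives, permutation). With peaks away from gene ends alone the excitatory list was at 10 and passed (adjusted p from 0.0372 to 0.329 over the 3, permutation).

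**Figure D3:**
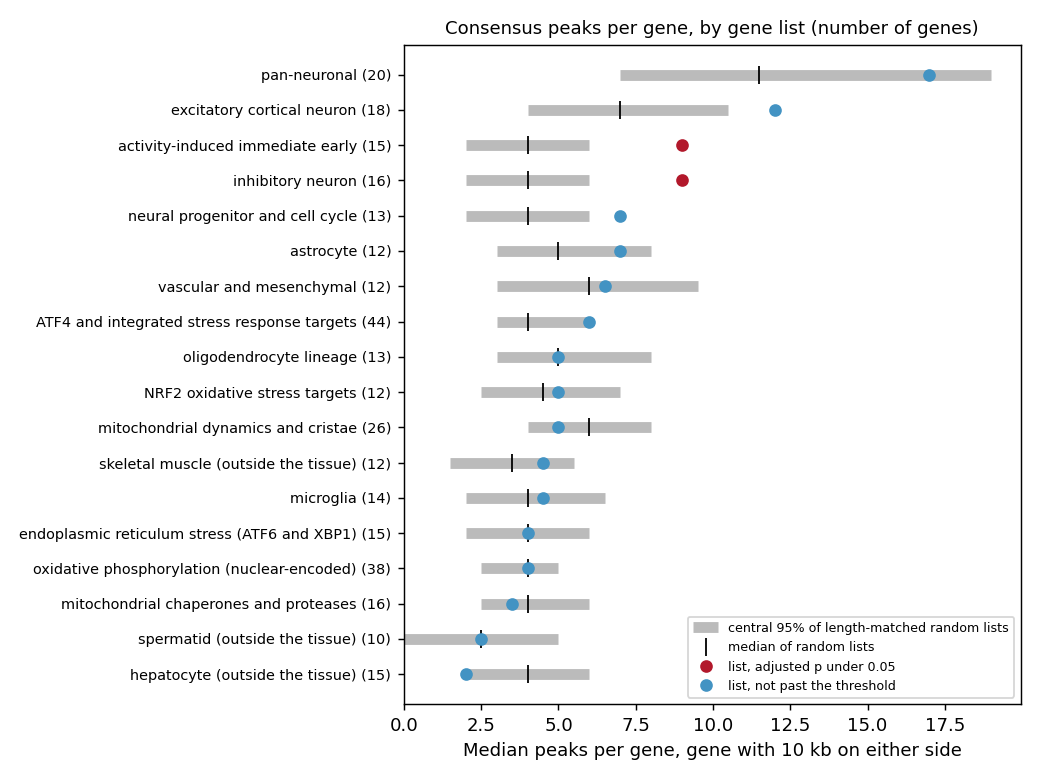
Median number of consensus peaks per gene, counted over the gene and 10 kb on either side, for the 18 lists with the number of genes in brackets; grey bars span the central 95% of 10000 length-matched random lists, ticks are their medians, and red points are lists past adjusted p 0.05. The inhibitory neuron and immediate early lists lie at 9 peaks against a random median of 4.

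Peaks concentrated at gene ends. Of the nuclear peaks, 20170 (9.53%) had their midpoint within 1000 bp of a protein-coding gene end, 3.22 times the share of sequence in those windows (95% block bootstrap interval 3.14 to 3.30). The insides of protein-coding genes held 101448 peaks at 1.29 times their share of sequence (1.27 to 1.32). Genes of other types held 17057 peaks at 1.02 times (0.986 to 1.06), and sequence between genes held 72999 peaks at 0.663 times (0.651 to 0.673). Gene-end peaks were wider, with a median of 811 bp against 414 bp elsewhere, and ranked wider on average in 1238 of 1286 blocks of 1 Mb (p = 1e-05, permutation test with the signs of block differences flipped, the smallest it can give). When a peak counted by any overlap, the ratio for genes of other types was 1.04 and its interval no longer included 1.

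Of the 10 widest peaks, 1 lay on a ribosomal RNA pseudogene and the others overlapped protein-coding genes. The widest, of 4410 bp (chromosome 17, 39842965 to 39847374), lay on Rn18s-rs5. Others lay on Stk11 and Cbarp (3467 bp), Tsc22d2 (3332 bp), the Wnt receptor gene Fzd8 (3171 bp), Zfp462 (3100 bp), Adgrb2 (3037 bp), Dlgap4 (3026 bp), Rreb1 (3006 bp) and Klhl29 (2975 bp).

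Autosomes held between 71.1 peaks per Mb (chromosome 3) and 110.2 (chromosome 11), and chromosome X held 21.6. The ratio of X to autosomes was 0.251 (95% block bootstrap interval 0.213 to 0.291). Of 963 protein-coding genes on X, 474 (49.2%) had a peak at an end, against 14842 of 20558 on autosomes (72.2%, p = 1.49e-48, two-sided Fisher's exact test, with genes as the units). In the 15 lists that are not from outside the tissue, all 8 genes on X had one, as did 251 of 276 on autosomes. The lower share on X was thus not seen among these few genes. Chromosome Y held 47 peaks. The labels do not give the sex of the embryos.

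**Figure D4:**
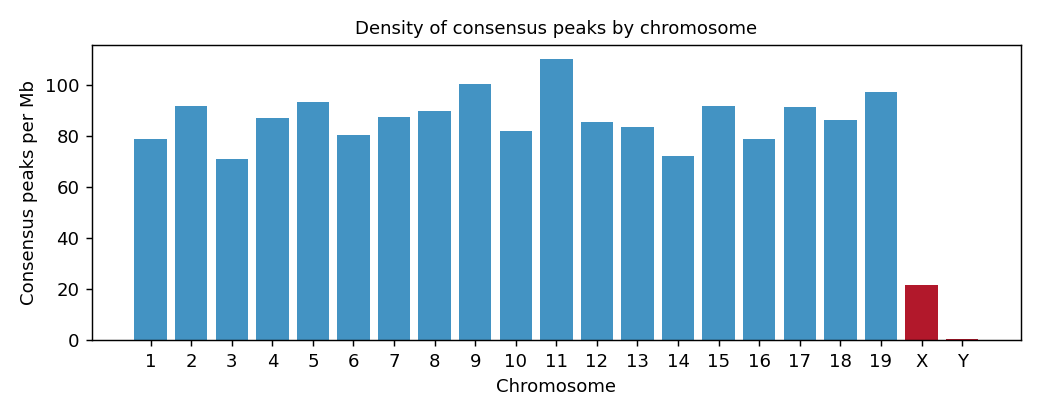
Consensus peaks per Mb for each nuclear chromosome, over the span from its first to its last peak or gene; autosomes are blue and X is red, and the bar of Y (0.519 per Mb) is too low to see. Autosomes lie between 71.1 and 110.2 peaks per Mb and X lies at 21.6.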

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

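The test in this part was chosen after the peaks it concerns had been seen. The mitochondrial genome, which no comparison uses, carried 8 peaks, more than the limit of 3 that a count of 0 allows. They covered 67.6% of its 16203 bp up to the last annotated feature or peak, against 20.9% of the windows around protein-coding gene ends and 4.12% of the nuclear chromosomes. The widest was 2820 bp, and the widest peak of the nuclear set, at 4410 bp, lay on a ribosomal RNA pseudogene. DNA present in many copies per cell may give such peaks along its length. The coverage of 67.6% restates the pattern that prompted this explanation, so it neither excludes nor supports it, and the explanation stays open. Nothing here bears on mitochondrial DNA under Opa1 knockdown, since the list names no sample or group. No biological explanation was tested, and how mitochondrial reads were filtered is not given in the sources used here.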

How the results depend on the processing

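Tests against length-matched and density-matched lists, without peaks at another gene's end, without receptor genes in the background and with scaffold genes were added after the data were seen. No paired analysis was possible because the list has no column per sample, although the groups share replicate numbers in the labels. Not run for the same reason were all alternatives for comparisons between groups, leaving out replicates among them. The motif alternatives and the CpG-matched lists were not run for want of a genome sequence, and the score, at its ceiling for 98.5% of peaks, gave no stricter set. Depth per sample is unknown, so a gene without a peak cannot be told from one whose peak was too shallow to call. Of 262 recomputed values over 46 results, 219 kept their direction and side of the threshold, or moved within their limits, and 43 did not. None changed direction past the threshold on both sides. The Atf4 target list stood above other genes in 9 of 9 alternatives. Where no reason is given below, the cause was not tested.

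The number of higher lists, 9 in the main setting, was 4 with 2500 bp windows, 2 against length-matched lists (Atf4 targets and oxidative phosphorylation) and 4 without receptor genes. Lower lists, 1 in the main setting, numbered 0 with 2500 bp windows, 3 with peaks of at least 500 bp and 2 with a peak over the end itself. With 2500 bp windows these were no longer past the threshold: chaperones and proteases (100% of genes), NRF2 targets (100%), excitatory (94.4%), progenitor (100%), immediate early (100%) and hepatocyte (53.3%). Against length-matched lists the shares stay as they were by construction, and the p doubles the smaller tail. There mitochondrial dynamics (96.2%), chaperones (100%), NRF2 (100%), excitatory (94.4%), pan-neuronal (100%), progenitor (100%) and immediate early genes (100%) were not past it. Against lists matched on neighbours within 100 kb, NRF2 (100%), excitatory (94.4%) and progenitor genes (100%) were not past it, which left 6 higher lists.

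Without receptor genes in the background, whose removal raises the share of other genes, chaperones (100%), NRF2 (100%), excitatory (94.4%), progenitor (100%) and immediate early genes (100%) fell out. Without peaks at another gene's end, chaperones (62.5%) and oxidative phosphorylation (63.2%) fell out and inhibitory markers entered (93.8%). Endoplasmic reticulum stress genes entered at 93.3% with 500 bp windows, with peaks of at least 500 bp and with a peak over the end, and inhibitory markers at 93.8% with 500 bp windows. Microglia genes were lower with peaks of at least 500 bp (28.6%) and with a peak over the end (21.4%), and spermatid genes with the wider peaks (20%). Progenitor genes with the wider peaks (84.6%) and immediate early genes with a peak over the end (73.3%) were not past the threshold.

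In peaks per gene, 50 kb flanks left 1 higher list, with inhibitory markers at 20.5 peaks, and peaks away from gene ends put excitatory markers past the threshold at 10 peaks. Counting any overlap gave a ratio of 1.04 for genes that are not protein-coding. The other class ratios, the width difference and the ratio of X to autosomes kept their calls under the alternatives fixed beforehand.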

Other observations

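The families and regions in this part were chosen after values had been seen, and the tests of muscle genes and chromosome X were written after those patterns were seen and before the test values, except the tests of muscle against other lists, which were added after. Among 16 gene families, shares at gene ends ran from 2.84% to 100%. Of 1109 olfactory receptor genes 75 had a peak (6.76%, exact 95% interval 5.36 to 8.40%), and of 352 vomeronasal receptor genes 10 (2.84%, 1.37 to 5.16%). Major urinary protein genes had one in 1 of 22 cases and beta-defensin genes in 7 of 42. All 16 ionotropic glutamate receptor genes had one (adjusted p = 0.00615, Fisher's exact test over the families). So did 76 of 78 mitochondrial ribosomal protein genes, 38 of 40 proteasome subunits and 72 of 77 ribosomal proteins (adjusted p = 2.22e-09, 0.000328 and 1.96e-06, Fisher's exact test). Hox genes, which pattern the body axis behind the forebrain, had one less often than other genes, in 19 of 39 cases (adjusted p = 0.00615, Fisher's exact test). So did interleukin genes (17 of 37) and chemokine genes (19 of 36), with adjusted p = 0.0028 and 0.0313 by Fisher's exact test. Of other gene types, 71.2% of tRNA genes, 56.0% of lncRNA genes and 13.4% of pseudogenes had a peak at an end.

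Potassium channel genes had a median of 10.5 peaks per gene against 6 in length-matched lists, and protocadherin genes 16 against 8. Zinc finger genes named Zfp had fewer, 3 against 5, although 340 of 397 had a peak at an end. Each of the 3 had p = 0.0002 by permutation, the smallest that 10000 random lists can give, and adjusted p = 0.00107. Clustered protocadherin genes overlap, so 1 peak is counted for several of them. By peaks above the mean of genes near in length, the first genes were Auts2 (204 peaks), the cadherin gene Cdh13 (200), Camta1 (190), Ptprn2 (189) and the reelin adaptor gene Dab1 (187), each against a mean of 75.7. The mean is shared because the longest genes draw on the same neighbours in length, so length is not closely matched for them. Skint5 and Skint6, of an immune family, span 521613 and 482358 bp and had 0 peaks. The densest 100 kb held 51 peaks and lay at Aqp12 and Kif1a, a motor of synaptic vesicle precursors (chromosome 1, 93000001 to 93100000). The next held 45 peaks at the start of chromosome 9 (3000001 to 3100000) and no protein-coding gene. Its peaks covered 10137 bp, against 24862 bp in the densest window. Chromosome Y had 26 of its 47 peaks past 90 Mb, between 90726046 and 90829379. No list of excluded regions is given in the sources used here, so whether such regions should have been removed is unknown.

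Chromosome X had 0.251 times the peaks per Mb of autosomes. Gene number does not account for it, since the ratio was 0.263 (95% interval 0.228 to 0.299) among 1 Mb blocks matched on protein-coding genes. If a lower X signal per cell dropped peaks near the calling threshold, narrow peaks would be lost first, but the ratio for peaks under 500 bp over that for wider ones was 1.09 (1.00 to 1.19), which met the bound written beforehand against it. Width stands in for signal there, which the file does not hold, so a loss of signal that also narrows wide peaks was not tested and stays open. The median width was 404 bp on X and 426 bp on autosomes, and 912 against 808 bp at gene ends, and no biological explanation was tested.

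Skeletal muscle genes had a peak at an end in 11 of 12 cases, against 4 of 15 hepatocyte genes (p = 0.00138, Fisher's exact test) and 20 of 20 pan-neuronal genes (p = 0.375, Fisher's exact test), though the list did not pass against all genes. Peaks of neighbouring genes may contribute. Without peaks within 1000 bp of another gene's end, 8 of 12 remained (66.7%, exact interval 34.9 to 90.1%), against 57.5% of other genes and 20 of 20 pan-neuronal genes (p = 0.0138, Fisher's exact test). The peaks left out can include a gene's own. Muscle genes had a median of 5 protein-coding neighbours within 100 kb against 1 for pan-neuronal genes, so the rule can remove more of theirs. The likeness to pan-neuronal genes was lost in the same way with peaks of at least 500 bp, a rule unrelated to neighbours (8 of 12 against 20 of 20), and with a peak over the end itself the shares were 58.3% and 85% (p = 0.116, Fisher's exact test), while under these 3 rules in turn the difference from hepatocyte genes had p = 0.0220, 0.0574 and 0.0369 (Fisher's exact test). Gene-dense surroundings are another candidate explanation, and the observed 91.7% equalled the upper bound of 91.7% in lists matched on neighbours within 100 kb, whose median was 75%. The condition written for it was thus met, but only 12 of 12 could have exceeded the bound, so these explanations cannot be told apart with 12 genes, and no biological one was tested.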
